A study of Mus musculus with 12 samples.

How the data were processed

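Poly(A) RNA of the cerebrum was sequenced from 12 male mice, 4 in each of 3 groups, with 1 library per mouse. The dissected tissue held cortex, hippocampus, striatum, thalamus and hypothalamus, and the mice had been perfused with saline. The mice carried a tetracycline operator at the Atg101 gene together with a silencer that doxycycline holds off the operator, so a diet with 0.01% doxycycline kept Atg101 on. Pre-suppression mice were sampled on doxycycline at 13 to 15 weeks of age. Suppressed mice were sampled after a further 4 weeks without doxycycline, at 17 to 19 weeks. Rescued mice had 4 weeks without doxycycline and then 4 weeks with it again, and were 21 to 23 weeks old. Age differed between all groups, and doxycycline on the day of sampling differed between the suppressed group and both others.

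Per the labels' protocols, the libraries came from poly(A) RNA and did not keep strand. Reads of overlapping or antisense genes can therefore not be told apart. HISAT2 2.0.5 and the builds GRCm38 and mm10 are named per the submitters' processing notes. The counting tool, its annotation and any filter on genes are not given in the sources used here. The deposited values were whole-number counts per gene for each library, with no normalization. The table held 25239 genes, the smallest total over the 12 libraries was 3, and 17 gene names occurred more than once. Of the columns of per-sample values 0 were left unused.

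Totals ranged from 18.9 to 25.9 M counts per library. In these libraries a count of 0 would allow up to 3 counts of the total, and such a floor covers counting error only. Library pairs within a group differed by 3.2 to 17.3 times the sampling variance (chi-square per degree of freedom), so no library was treated as a duplicate.

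Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr, which left 16850 genes, and libraries were scaled by the TMM method. All 12 libraries entered 1 quasi-likelihood fit with a term for the group, and the 3 groups shared 1 estimate of the spread. The 3 contrasts between groups were tested two-sided with edgeR's quasi-likelihood test and adjusted by Benjamini-Hochberg over the genes tested. Every adjusted p given for a gene is of this kind unless another tool is named. An adjusted p under 0.05 was taken as passing. Counts scaled to 1 M per library (CPM, M for mega) used the TMM-scaled totals and are given as mean ± SD over 4 mice. Log2 fold changes are given ± SE. Atg101 was also tested by exact two-sided permutation of the log2 CPM of 4 against 4 mice.

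The 49 gene lists, with 1310 entries and 1224 different genes, were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on voom values, at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 49 lists of a comparison. Every camera call is also given with the correlation estimated per list, which is the stricter setting, and fry was run as a self-contained test. Of the list genes 1195 were measured. A list's score in a mouse was the mean over its members of log2 CPM, relative to the mean of the pre-suppression mice.

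Genes were named by a fixed rule. It took Atg101 and the ULK1 complex. It took the 10 genes with the largest rise and the 10 with the largest fall among genes that passed, had a mean log2 CPM of at least 0 and did not overlap between groups. It then took leading members of the gene lists up to 30 genes per comparison, and the nearest measured neighbours of Atg101. A gene named in 1 comparison could be given its values in the others. Where fewer than 5 genes passed, the 5 rising and 5 falling genes of smallest p were named as not having passed. Other genes were chosen after their values were seen and are marked as such. Coordinates are from GENCODE release M21 on GRCm38, matched by gene identifier for 25223 of the 25239 genes.

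The procedure was tested on simulated counts drawn from the means and library sizes of these libraries, with 200 of 16850 genes changed. Over 3 simulations, the suppressed against pre-suppression contrast recovered 17.1% of changes of 1.25-fold, 52.5% of 1.5-fold and 82.7% of 2-fold, and 6.21% of its 322 calls were false. The rescued against suppressed contrast recovered 17.1%, 54.5% and 82.2%, and 4.39% of its 319 calls were false. The rescued against pre-suppression contrast, simulated with no change, gave 0 calls.

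The return of a gene was minus its log2 fold change between rescued and suppressed mice, divided by its log2 fold change between suppressed and pre-suppression mice; 1 is the pre-suppression level and 0 the suppressed level. Alternatives were DESeq2 size factors, no filter on low counts, a fit of the 8 libraries compared, the mouse number in the titles as a block, DESeq2 1.42.0, limma-voom, and each library left out in turn. Scaling without mitochondrially encoded and ribosomal protein genes, and a fit without 3 libraries that stood apart from their groups, were added after seeing the data.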

Results

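RNA of the whole cerebrum was counted in 12 male mice in which transcription of Atg101 can be switched off and on again through doxycycline in the diet. The 3 groups of 4 mice were sampled before suppression, after 4 weeks of suppression, and after 4 weeks of suppression followed by 4 weeks of rescue. Library totals were 20 to 24.7 M counts in the pre-suppression, 20 to 25.9 M in the suppressed and 18.9 to 22.3 M in the rescued mice. The first principal component held 24% of the variance. On it the pre-suppression mice lay between -18.1 and -15.5, suppressed mice 1, 2 and 4 between 18.5 and 23.8, and suppressed mouse 3 at -8.66. Rescued mice 1 and 3 lay at -17.3 and -14.8, and rescued mice 2 and 4 at 26.7 and 16.7.

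Atg101, which encodes a subunit of the ULK1 complex that starts autophagosome formation, was nearly silenced in every suppressed mouse and back on in every rescued mouse. The gene (ENSMUSG00000037204; GRCm38 chromosome 15, 101284272 to 101290945, plus strand, protein-coding) had 7.62 ± 0.85 CPM before suppression, 0.296 ± 0.17 CPM after it and 8.99 ± 0.60 CPM after rescue (SD, n = 4 mice each). The suppressed level was 3.88% of the pre-suppression level, from 1 to 9 counts per library against 157 to 192. The log2 fold change was -4.63 ± 0.25 (edgeR, adjusted p = 1.27e-07) with suppression and 4.87 ± 0.24 (adjusted p = 5.57e-08) with rescue. Exact two-sided permutation tests gave p = 0.0286 for both, the smallest value that 4 against 4 mice allow. Rescued mice held 118% of the pre-suppression level, a difference that was not detected (log2 fold change 0.24 ± 0.16, edgeR adjusted p = 0.675; exact permutation p = 0.0571). Of 12 other genes tested within 500 kb, 0 passed in any of the 3 comparisons, and 3 had an unadjusted p under 0.05 between suppressed and pre-suppression mice. These 3, chosen after their values were seen, were Grasp (0.72 ± 0.21, edgeR adjusted p = 0.0601), Slc4a8 (-0.11 ± 0.05, adjusted p = 0.241) and Krt75 (4.47 ± 1.41, adjusted p = 0.0871). Krt75 had a mean log2 CPM of only -1.94. A change of genes near Atg101 was thus not detected but not excluded. The nearest measured neighbours, Nr4a1 upstream and Gm35853 downstream (annotated as antisense), differed by -0.43 ± 0.41 and 1.13 ± 0.58 on the log2 scale with suppression.

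The comparison of suppressed with pre-suppression mice asked which transcripts differ once Atg101 is off. The suppressed cerebrum had more mRNA of the iron genes Tfrc and Fth1. By camera at the preset correlation it also had more mRNA of the lists of ATF4 targets, cytosolic ribosomal proteins, mitochondrially encoded genes, cholesterol synthesis and reactive astrocytes. None of these 5 lists was called with an estimated correlation (adjusted p = 0.0799 to 0.196), and not all of their genes passed. Tfrc (GRCm38 chromosome 16, 32608920 to 32632794, plus strand), the transferrin receptor, went from 106 ± 22.8 to 417 ± 23.5 CPM, a log2 fold change of 1.98 ± 0.17 (edgeR, adjusted p = 3.73e-05). Fth1, the ferritin heavy chain, rose by 0.62 ± 0.06 on the log2 scale (adjusted p = 6.41e-05), and Sqstm1, an autophagy receptor that is itself degraded by autophagy, by 0.49 ± 0.05 (adjusted p = 8.64e-05). Further large rises were those of the protease inhibitor Serpine1 (2.17 ± 0.42), the cell cycle inhibitor Cdkn1a (1.78 ± 0.29) and the secreted glycoprotein Stc2 (1.57 ± 0.25). The cytokine Lif (1.96 ± 0.48), the astrocyte filament Gfap (1.89 ± 0.43) and the neurotrophin Bdnf (1.62 ± 0.35) also rose. The largest fall after Atg101 was that of the neurotrophin Ntf3 (-1.31 ± 0.33), and Wnt9a, a Wnt ligand, fell by 0.81 ± 0.12. In all, 714 of 16850 genes passed, 438 higher and 276 lower. Of these 153 changed more than 1.5-fold, 127 upward and 26 downward. At an unadjusted p under 0.05 there were 3425 genes, against 842 expected by chance.

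Many genes of the integrated stress response rose. Of 32 measured ATF4 targets 17 rose, 0 fell and 15 did not pass (26 rose adjusted over the list alone; camera adjusted p = 9.9e-17, and adjusted p = 0.196 with an estimated correlation). Atf4 itself, the transcription factor of this response, rose from 95.6 to 162 CPM (log2 fold change 0.76 ± 0.09). Chac1, a glutathione-degrading enzyme, rose by 1.45 ± 0.22. Slc7a5, an amino acid transporter, rose by 0.83 ± 0.13 and Trib3, a pseudokinase, by 1.63 ± 0.33. The last 2 were chosen after their values were seen. The ATF4 scores of the 4 suppressed mice were 0.978, 0.498, 0.201 and 0.724, lowest in mouse 3. Cytosolic ribosomal protein genes rose by little but nearly all together. Of 76 genes 63 rose and 0 fell (70 adjusted over the list alone), with a median log2 fold change of 0.37 (camera adjusted p = 1.96e-65; adjusted p = 0.0799 with an estimated correlation). Rpl9 rose by 0.60 ± 0.06, Rps12 by 0.51 ± 0.05, Rpl12 by 0.48 ± 0.05 and Rpl26 by 0.43 ± 0.05. Ribosomal protein genes have many pseudogene copies, so single members are uncertain. Of 12 mitochondrially encoded genes 10 rose and 0 fell (11 adjusted over the list alone; camera adjusted p = 2.4e-14, adjusted p = 0.121 with an estimated correlation), among them mt-Cytb (0.46 ± 0.06) and mt-Nd4 (0.38 ± 0.05). mt-Atp6 (1.73 ± 0.37) overlaps mt-Atp8, and the chromosome 1 pseudogene Gm28438 rose with it (1.70 ± 0.36), which leaves the reads of these genes uncertain. The mitochondrially encoded share of all counts was 4.92 ± 0.363% in suppressed and 3.95 ± 0.162% in pre-suppression mice (exact permutation p = 0.0286, n = 4 each). In the nuclear oxidative phosphorylation list 4 of 63 genes rose and 0 fell (11 rose and 2 fell adjusted over the list alone; camera adjusted p = 8.44e-06, adjusted p = 0.497 with an estimated correlation), with Cox4i1 at 0.34 ± 0.04. Cholesterol synthesis genes rose in 13 of 24 cases and fell in 0 (18 adjusted over the list alone; camera adjusted p = 7.88e-14, adjusted p = 0.196 with an estimated correlation), for example Fdft1 (0.63 ± 0.10) and Hmgcs1 (0.64 ± 0.12), both chosen after their values were seen.

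Glial and immune genes rose unevenly between mice. In the reactive astrocyte list 9 of 31 genes rose and 0 fell (21 adjusted over the list alone; camera adjusted p = 8.12e-10, adjusted p = 0.196 with an estimated correlation). Gfap stood at 189 ± 11.9 CPM before and 700 ± 364 CPM after suppression. The complement gene C4b rose by 1.27 ± 0.22. The oncostatin M receptor Osmr, chosen after its values were seen, rose by 1.31 ± 0.24. The reactive astrocyte scores were 0.918, 1.23 and 0.928 in suppressed mice 1, 2 and 4 and 0.112 in mouse 3, within the range of the pre-suppression mice (up to 0.169). The general astrocyte markers did not move as a list (1 of 20 rose, 1 adjusted over the list alone, median -0.01; camera adjusted p = 0.939). Disease-associated microglia genes rose in 6 of 24 cases (13 rose and 1 fell adjusted over the list alone; camera adjusted p = 9.56e-08, adjusted p = 0.196 with an estimated correlation). Complement genes rose in 5 of 17 (8 adjusted over the list alone; camera adjusted p = 5.25e-05, adjusted p = 0.196 with an estimated correlation), with C1qa at 0.47 ± 0.10 and C1qc at 0.37 ± 0.08. Homeostatic microglia genes went both ways, with 4 of 24 higher and 2 lower (4 and 3 adjusted over the list alone; camera adjusted p = 0.472). Among them the purine receptor P2ry12 fell by 0.53 ± 0.08 and the lectin Siglech by 0.39 ± 0.08, both chosen after their values were seen. Interferon response genes rose in 4 of 30 cases (14 adjusted over the list alone; camera adjusted p = 2.55e-07, adjusted p = 0.388 with an estimated correlation). The interferon score was 1.45 in suppressed mouse 4 against 0.239 to 0.347 in the other 3. In the MHC class I list 4 of 19 genes rose (8 adjusted over the list alone; camera adjusted p = 7.1e-05, adjusted p = 0.302 with an estimated correlation). The MHC class I score was 0.843 in suppressed mouse 4 and 0.369, 0.268 and 0.118 in mice 1, 2 and 3. In the glucocorticoid response list 6 of 16 rose (10 adjusted over the list alone; camera adjusted p = 6.16e-08, adjusted p = 0.196 with an estimated correlation). Neuropeptide and granin genes rose in 6 of 26 cases (8 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.000107, adjusted p = 0.196 with an estimated correlation). Among them were Nptx2, a synaptic pentraxin (2.15 ± 0.52), and Penk, the enkephalin precursor (0.88 ± 0.12), chosen after its values were seen. The neuropeptide scores were 0.442, 0.534 and 0.458 in suppressed mice 1, 2 and 4 and 0.117 in mouse 3.

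General neuronal markers and core autophagy genes moved little, while lists of some neuron types and of some other cell types were lower. Of 24 general neuronal markers 0 passed, also adjusted over the list alone (median -0.02; camera adjusted p = 0.674), with 0 called by edgeR although 3425 of all genes had an unadjusted p under 0.05. Postsynaptic genes were lower as a list, with 2 of 36 passing, both lower (7 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.000614, adjusted p = 0.196 with an estimated correlation). These were the glutamate receptor subunit Gria4 (-0.30 ± 0.06) and the synaptic adhesion gene Nlgn3 (-0.27 ± 0.07), both chosen after their values were seen. Cortical markers were lower too, with 2 of 19 passing (7 adjusted over the list alone; camera adjusted p = 0.00141, adjusted p = 0.196 with an estimated correlation), including the layer marker Rorb (-0.31 ± 0.08). Inhibitory neuron markers were lower with 1 of 22 passing, the transcription factor Arx, chosen after its values were seen (6 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0137, adjusted p = 0.277 with an estimated correlation). This list was not called without pre-suppression mouse 3 (camera adjusted p = 0.0872) or suppressed mouse 1 (0.0803). Of 24 choroid plexus and ependymal genes 19 were negative (camera adjusted p = 0.0137, 0.311 with an estimated correlation). So were 14 of 20 oligodendrocyte precursor genes (0.0293 and 0.196) and 17 of 25 myelinating oligodendrocyte genes (0.0461 and 0.727). In edgeR 0, 0 and 2 of these genes passed as lower, and 1 myelin gene as higher. Each of the 3 lists lost its call when some library was left out. Chaperones of the ER unfolded protein response were lower as a list, with 1 of 25 passing (5 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00342, adjusted p = 0.497 with an estimated correlation), namely Calr, an ER calcium-binding chaperone (-0.54 ± 0.11). Within the ULK1 complex Ulk2, a kinase subunit, fell by 0.24 ± 0.05 (edgeR adjusted p = 0.0161), while Ulk1 (0.06 ± 0.07), Rb1cc1 (-0.15 ± 0.06) and Atg13 (-0.03 ± 0.06) did not pass. With Atg101, 2 of the 5 members fell (3 adjusted over the list alone; camera adjusted p = 0.00176, adjusted p = 0.121 with an estimated correlation). In the core autophagy list 1 of 42 genes rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.852), namely Becn1 (0.30 ± 0.06, chosen after its values were seen) and Ulk2. Selective autophagy receptors rose in 2 of 19 cases, also adjusted over the list alone, namely Sqstm1 and Nbr1 (0.26 ± 0.06, chosen after its values were seen); fry called the list (adjusted p = 0.000822) and camera did not (adjusted p = 0.0861). In all 26 of 49 lists passed, 18 higher and 8 lower, while other splits of the same 8 mice into 4 and 4 gave up to 30. Of the 49, 0 passed with an estimated correlation and 17 with fry, 15 of them in both camera and fry.

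The number of genes called depended on single mice. It was 312, 290, 375 and 416 without pre-suppression mouse 1, 2, 3 and 4, 439, 402 and 335 without suppressed mouse 1, 2 and 4, and 1386 without suppressed mouse 3. It was 2153 without the 3 mice apart on the first component. Of 31 named genes that passed, 17 kept an adjusted p under 0.05 whichever of the 12 libraries was left out, among them Tfrc, Fth1, Sqstm1, Atf4, Serpine1, Cdkn1a, Stc2 and Wnt9a. Gfap did not pass without pre-suppression mouse 1, 2, 3 or 4 (edgeR adjusted p = 0.0682, 0.0663, 0.0638 and 0.0642) or suppressed mouse 1, 2 or 4 (0.0627, 0.0525 and 0.057). Nor did Bdnf without pre-suppression mouse 1, 2 or 3 (0.0658, 0.0565 and 0.0603) or suppressed mouse 1 or 2 (0.0544 and 0.0503). For Lif this held of pre-suppression mice 1 to 4 (0.104, 0.0688, 0.0988 and 0.0592) and suppressed mice 1 and 2 (0.0698 and 0.109). For mt-Atp6 it held of pre-suppression mice 1 to 3 (0.0578, 0.0617 and 0.0591) and suppressed mouse 4 (0.0635). For Gm28438 it held of pre-suppression mouse 2 (0.0539) and for Ulk2 of pre-suppression mouse 1 (0.0634) and suppressed mouse 4 (0.0535). Ntf3 did not pass without pre-suppression mouse 1, 2, 3 or 4 (0.0921, 0.0581, 0.105 and 0.0826) or suppressed mouse 1, 2 or 4 (0.0747, 0.105 and 0.0888). Suppressed mice were off doxycycline, which cannot be separated from Atg101 here. They were also 4 weeks older, and for genes that did not return in the still older rescued mice age is not separated either.

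**Figure D1:**
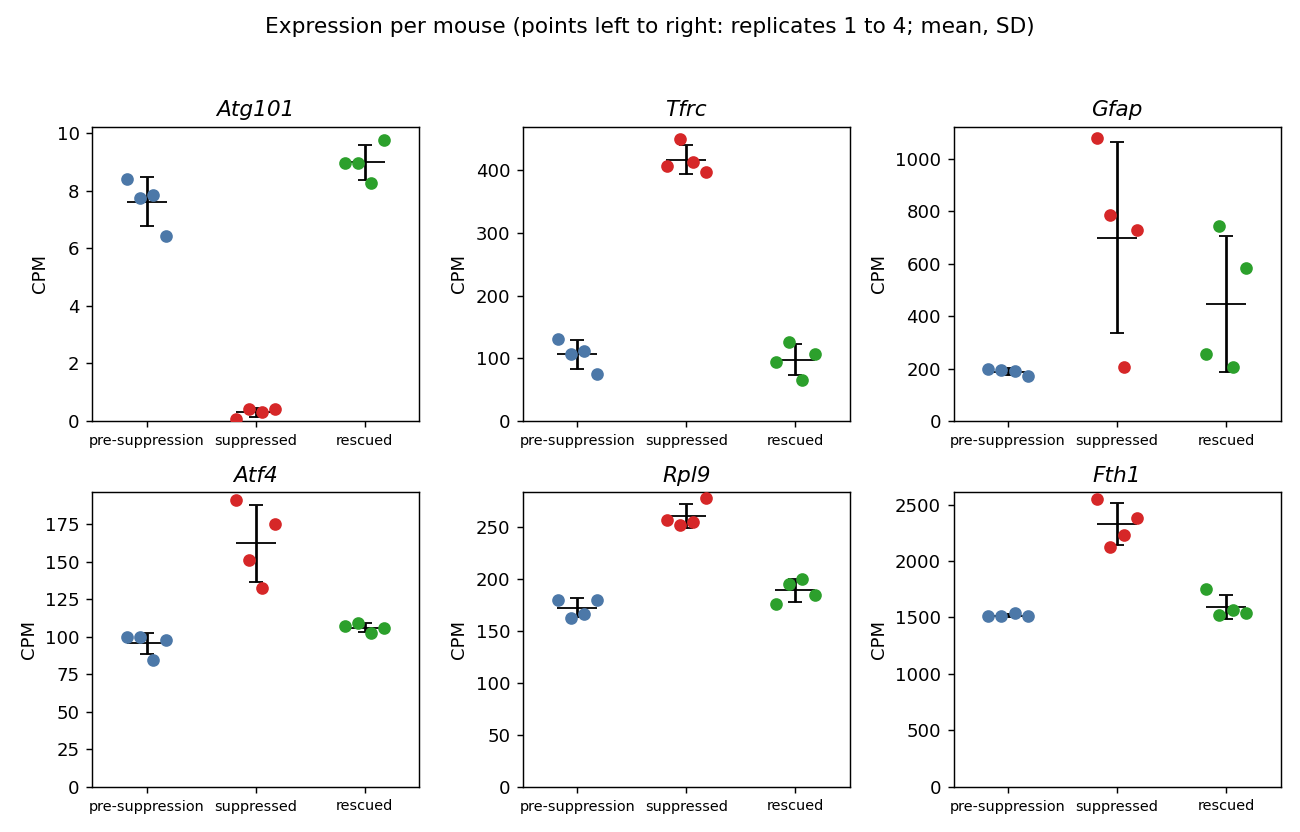
CPM of Atg101, Tfrc, Gfap, Atf4, Rpl9 and Fth1 in each of the 12 mice by group (points), with the mean and SD of 4 mice (bars), on linear axes that start at 0. Tfrc stood at 417 ± 23.5 CPM in the suppressed group against 106 ± 22.8 before and 98.0 ± 25.4 after rescue, while Gfap ranged widely among suppressed mice (700 ± 364).

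**Figure D2:**
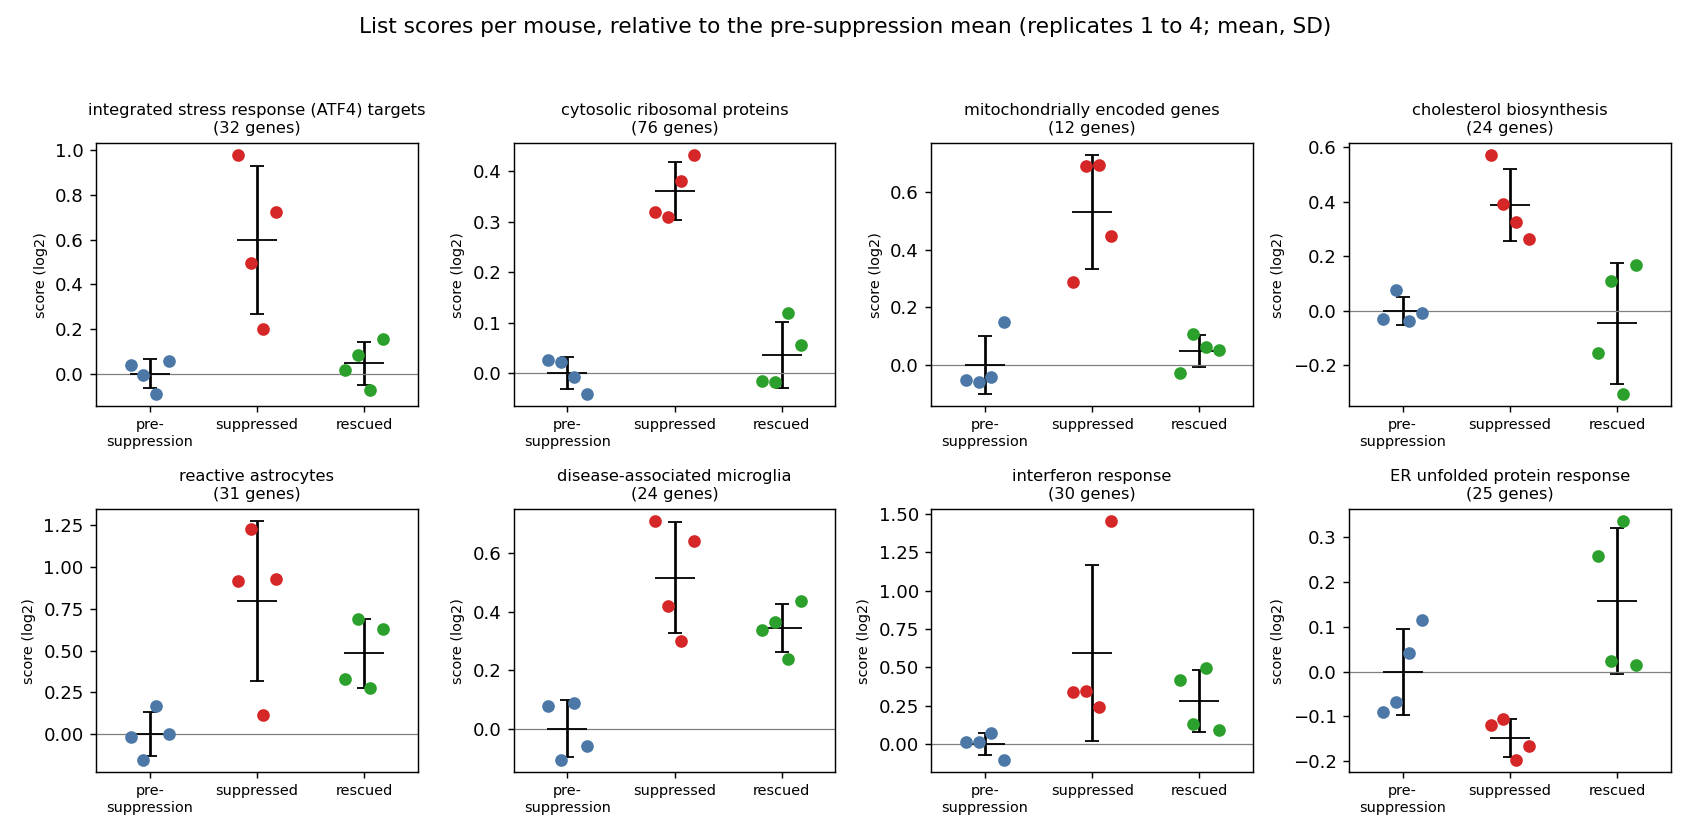
Scores of 8 gene lists in each of the 12 mice (points; mean log2 CPM of the members relative to the pre-suppression mean), with mean and SD per group (bars). The ribosomal protein score lay between 0.309 and 0.431 in the suppressed mice, and the reactive astrocyte score was 0.112 in suppressed mouse 3 and 0.691 and 0.63 in rescued mice 2 and 4.

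The comparison of rescued with suppressed mice asked what follows when Atg101 is switched on again. Most genes that passed went down, Tfrc among them. By camera at the preset correlation the lists of ATF4 targets, ribosomal proteins, mitochondrially encoded genes and cholesterol synthesis were lower and that of the ER unfolded protein response higher. With an estimated correlation only the ribosomal protein list was called (adjusted p = 0.0483; the others 0.0999 to 0.18). Tfrc fell by 2.09 ± 0.17 on the log2 scale (edgeR, adjusted p = 2.83e-05) to 98.0 ± 25.4 CPM, Fth1 by 0.54 ± 0.06 and Sqstm1 by 0.43 ± 0.05. Other large falls were those of the folate enzyme Mthfd2 (-1.25 ± 0.23), Chac1 (-1.18 ± 0.22), the translation repressor Eif4ebp1 (-1.07 ± 0.20) and the transcription factor Atf5 (-0.94 ± 0.16), all 4 on the ATF4 target list. After Atg101 the largest rises included Fmod, a matrix proteoglycan (1.35 ± 0.19, adjusted p = 0.00196), the Wnt ligand Wnt6 (1.14 ± 0.23), the ER chaperones Hspa5 (0.88 ± 0.18, adjusted p = 0.0233) and Calr (0.79 ± 0.11, adjusted p = 0.00146), and Sdf2l1 (0.92 ± 0.22). The meninges and fibroblast list was higher too, with 2 of 24 passing, Ogn, a matrix proteoglycan (0.93 ± 0.21), and Igfbp2, chosen after its values were seen (2 adjusted over the list alone; camera adjusted p = 0.0301, adjusted p = 0.637 with an estimated correlation). It was not called without suppressed mouse 3 (camera adjusted p = 0.438) or rescued mouse 1 (0.0522) or 4 (0.144), and without the 3 mice apart on the first component its median was -0.006. Ogn did not pass without pre-suppression mouse 1 or 4 (edgeR adjusted p = 0.0626 and 0.0576), suppressed mouse 1, 2 or 4 (0.0707, 0.118 and 0.123) or rescued mouse 1, 3 or 4 (0.124, 0.0934 and 0.0715). In all, 263 genes passed, 64 higher and 199 lower, and 44 changed more than 1.5-fold, 15 upward and 29 downward. At an unadjusted p under 0.05 there were 2231 genes against 842 expected by chance.

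ATF4 targets fell in 9 of 32 cases and rose in 0 (25 fell adjusted over the list alone; camera adjusted p = 3e-20, adjusted p = 0.18 with an estimated correlation), with Atf4 itself at -0.61 ± 0.09. Ribosomal protein genes fell in 55 of 76 cases and rose in 0 (69 adjusted over the list alone; camera adjusted p = 3.56e-76), the only list of the 49 that also passed with an estimated correlation (adjusted p = 0.0483). Rpl37 fell by 0.57 ± 0.07, Rpl9 by 0.46 ± 0.05, Rps12 by 0.45 ± 0.05 and Rps24 by 0.39 ± 0.05. Mitochondrially encoded genes fell in 7 of 12 cases (12 adjusted over the list alone; camera adjusted p = 1.76e-15, adjusted p = 0.0999 with an estimated correlation), and their share of counts was 4.14 ± 0.112% after rescue against 4.92 ± 0.363% before it (exact permutation p = 0.0286, n = 4 each). Cholesterol synthesis genes fell in 10 of 24 cases (21 fell and 1 rose adjusted over the list alone; camera adjusted p = 6.61e-20, adjusted p = 0.18 with an estimated correlation), among them the sterol methyl oxidase Msmo1 (-0.71 ± 0.11). Of the 25 genes of the ER unfolded protein response 7 rose and 0 fell (16 adjusted over the list alone; camera adjusted p = 7.12e-11, adjusted p = 0.18 with an estimated correlation). The scores of rescued mice 1 and 3 were 0.259 and 0.336, those of mice 2 and 4 0.023 and 0.016. Homeostatic microglia genes rose in 3 of 24 cases (4 adjusted over the list alone; camera adjusted p = 4.49e-06, adjusted p = 0.18 with an estimated correlation), namely P2ry12 (0.49 ± 0.08), the fractalkine receptor Cx3cr1 (0.36 ± 0.06) and Siglech (0.42 ± 0.08), chosen after their values were seen. In a fit without the 3 mice apart on the first component this list did not pass (adjusted p = 0.0509). The reactive astrocyte list was lower, but with 0 of its 31 genes passing in edgeR, also adjusted over the list alone (camera adjusted p = 0.00421, adjusted p = 0.637 with an estimated correlation, and adjusted p = 0.142 without suppressed mouse 2). Its scores were 0.332, 0.691, 0.277 and 0.63 in the 4 rescued mice. The interferon response list was likewise lower with 0 of 30 genes passing, also adjusted over the list alone (camera adjusted p = 0.00517, adjusted p = 0.745 with an estimated correlation), and was not called without suppressed mouse 4 (adjusted p = 0.966). In all 20 of 49 lists passed, 7 higher and 13 lower, while other splits of the same 8 mice into 4 and 4 gave up to 26. Of the 49, 1 passed with an estimated correlation and 9 with fry, 8 of them in both camera and fry.

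The count of 263 genes was 86 when only the 8 libraries compared were fitted, and 175, 163, 138 and 173 without suppressed mouse 1 or 4 or rescued mouse 1 or 4. It was 1229 without the 3 mice apart on the first component. DESeq2 called 192 genes higher and 355 lower (35.1% higher, against 24.3% in edgeR). Of 30 named genes that passed, 18 did so whichever library was left out, among them Tfrc, Fth1, Sqstm1, Mthfd2, Chac1, Eif4ebp1, Atf5, Fmod and Calr. Hspa5 did not pass without suppressed mouse 1 or 4 (edgeR adjusted p = 0.0654 and 0.0676) or rescued mouse 1 or 3 (0.0784 and 0.0569), nor Wnt6 without suppressed mouse 4 (0.0613) or rescued mouse 1 (0.0711). Sdf2l1 kept its call only without pre-suppression mouse 4 or rescued mouse 2 or 4, with adjusted p from 0.0599 (without pre-suppression mouse 3) to 0.145 (without rescued mouse 1) when one of the others was left out.

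Genes that suppression had changed mostly moved back. Of the 714 genes 704 had a rescued value on the pre-suppression side of the suppressed value. Of the 714, 207 (29%) were called in the opposite direction between rescued and suppressed mice, against 6.22 for independent lists. Conversely, 56 of the 263 genes called there had not been called before. The median return was 0.70 (quartiles 0.497 to 0.886; jackknife SE 0.169). It was 0.91 for the 17 ATF4 targets called, 0.96 for the 13 cholesterol synthesis genes, 0.88 for the 63 ribosomal protein genes and 0.81 for the 10 mitochondrially encoded genes. It was 0.51 for the 9 reactive astrocyte genes, 0.44 for the 6 neuropeptide genes, 0.40 for the 6 disease-associated microglia genes and 0.13 for the 5 complement genes. The neuropeptide scores were 0.011 and 0.083 in rescued mice 1 and 3 and 0.456 and 0.409 in mice 2 and 4, so that this return is a mean over unlike mice. The differences between lists were not tested. Both fold changes use the same suppressed libraries, which alone gives a return. In 20 simulations of unchanged groups the 714 genes of smallest p had a mean median return of 0.497, and 89.8% of them moved back. These simulations called a mean of 0.2 genes with suppression and 0.4 with rescue. They therefore cannot say how many of the 207 genes called back the shared libraries alone would give. Nor is their return of 0.497 a baseline for the 0.70 of genes that passed. The suppressed mice were also split 2 and 2, so that the fold changes shared no suppressed library. The median return then averaged 0.517 (0.132 to 0.836 over 6 splits). With suppressed mouse 3 among the mice compared with pre-suppression mice, it was 0.768, 0.836 and 0.69 (136 to 164 genes called). With mouse 3 among those compared with rescued mice, it was 0.368, 0.31 and 0.132 (569 to 1112 genes called). The mean of 0.517 therefore joins unlike splits. On average 64 genes were called back and 87.7% of the genes called moved back (62.8 to 98.7%). Across genes, which are not independent replicates, the covariance of the fold changes was -0.0447, against -0.0222 in the simulations and -0.0194 on average in the splits. The correlation was -0.543, against -0.494 and -0.186.

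**Figure D3:**
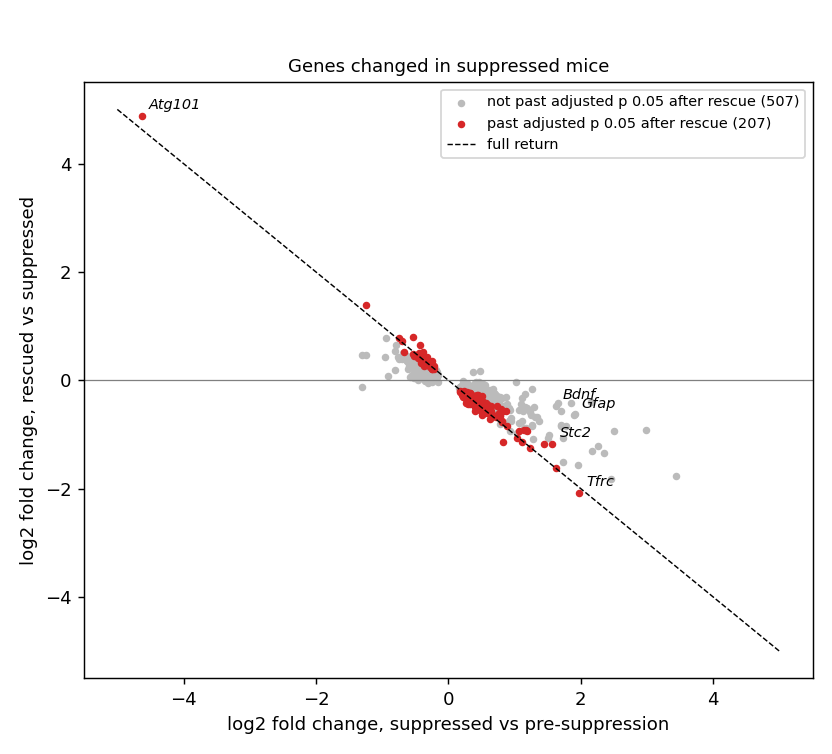
Log2 fold change of rescued against suppressed mice (vertical) over that of suppressed against pre-suppression mice (horizontal) for the 714 genes changed by suppression, with the line of full return. Of these genes 704 moved back and 207 were called back; both axes share the suppressed libraries.

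The comparison of rescued with pre-suppression mice asked what remained different after Atg101 had been off and on again. No single gene passed in edgeR (0 of 16850; smallest adjusted p = 0.205), although 1583 had an unadjusted p under 0.05 against 842 expected by chance. Here limma-voom called 0 and DESeq2 20, 8 higher and 12 lower. None of the genes named here for this comparison passed in edgeR. C1qc, a chain of the complement starter C1q, had the smallest p, with 28.3 CPM before suppression, 36.5 CPM after it and 40.5 CPM after rescue (log2 fold change 0.51 ± 0.08, edgeR adjusted p = 0.205). Next among positive differences were those of Sgsm1 (0.47 ± 0.08), the retinoic acid hydroxylase Cyp26b1 (0.62 ± 0.11), the Fc receptor Fcgr3 (0.65 ± 0.12) and C4b (1.1 ± 0.22). Among negative differences the next were those of Hecw2 (-0.34 ± 0.06), Zbtb37 (-0.43 ± 0.08), Wnt9a (-0.62 ± 0.12), Mlip (-0.38 ± 0.08) and Zdhhc21 (-0.27 ± 0.05). DESeq2 called all of these 10 genes, with adjusted p = 0.00013 for C1qc. Tfrc, which had risen with suppression, stood at -0.11 ± 0.17 (edgeR adjusted p = 0.867).

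As lists, microglial, immune and meningeal genes were higher by camera at the preset correlation in rescued than in pre-suppression mice. Of 24 homeostatic microglia genes 23 had a positive difference, with a median log2 fold change of 0.16 (camera adjusted p = 2.49e-10, adjusted p = 0.204 with an estimated correlation; fry adjusted p = 0.0494). Of these 0 passed over all genes and 10 passed adjusted over the list alone. The scores of the 4 rescued mice ranged from 0.191 to 0.291, those of the pre-suppression mice from -0.04 to 0.046. All 17 complement genes were positive (4 passing adjusted over the list alone; camera adjusted p = 1.73e-07, adjusted p = 0.257 with an estimated correlation). So were 21 of 24 disease-associated microglia genes (0 adjusted over the list alone; camera adjusted p = 2.27e-06, adjusted p = 0.274 with an estimated correlation) and 29 of 31 reactive astrocyte genes (1 adjusted over the list alone; camera adjusted p = 2.07e-06, adjusted p = 0.431 with an estimated correlation). Other cell types were higher as well: 19 of 24 meninges and fibroblast genes were positive, with a median of 0.292 (4 adjusted over the list alone; camera adjusted p = 1.49e-05, adjusted p = 0.431 with an estimated correlation). Of 15 perivascular macrophage and leukocyte genes 11 were positive, with a median of 0.389 (2 adjusted over the list alone; camera adjusted p = 0.000827, adjusted p = 0.431 with an estimated correlation). Cortical markers were lower, 16 of 19 being negative (1 adjusted over the list alone; camera adjusted p = 1.39e-05, adjusted p = 0.245 with an estimated correlation, and adjusted p = 0.0579 without the 3 mice apart on the first component). Choroid plexus and ependymal genes were lower too, 20 of 24 being negative (0 adjusted over the list alone; camera adjusted p = 0.000906, adjusted p = 0.413 with an estimated correlation). In all 22 of 49 lists passed, 19 higher and 3 lower, while other splits of the same 8 mice into 4 and 4 gave up to 23. Of the 49, 0 passed with an estimated correlation and 1 with fry. Of the 714 genes changed by suppression 0 were still called after rescue in edgeR (14 in DESeq2), and 625 (87.5%) had the same sign in both. The pre-suppression mice were also split 2 and 2, so that the fold changes shared no pre-suppression library. Then 76.5% of the genes called had the same sign on average (69 to 81.6%). Simulations of unchanged groups that share these libraries gave 89.6% for the 714 genes of smallest p. They called a mean of only 0.2 genes with suppression, so they give no baseline for called genes. Across genes the covariance of these fold changes was 0.0557, against 0.0221 in the simulations and 0.0374 on average with the pre-suppression mice split 2 and 2. The count of 0 became 1 without pre-suppression mouse 4 (Hspa1b, chosen after its values were seen) and 1 without suppressed mouse 2 (Sgsm1), and 3 when only the 8 libraries compared were fitted (Sgsm1, C4b and C1qc). Rescued mice were 8 weeks older than pre-suppression mice, and age cannot be separated from the history of suppression here.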

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

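Of the tests in this part, that of gene length and GC content was fixed before its result was seen; all the others were chosen only after the results they bear on were seen. Among 411 sets of 4 mice per group, 23 held a mouse far from the other 3, measured by its gap to the nearest of them relative to the range of the 4, against 20.6 that chance gives (about 1 in 20).

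In single genes, as log2 CPM, pre-suppression mouse 1 was low for Gm28438 (1.89, others 4.3 to 4.7), Slc7a3 (2.95, others 3.22 to 3.24) and Gm35853 (-0.21, others 0.24 to 0.31) and high for H2-D1 (5.57, others 5.32 to 5.35). Pre-suppression mouse 2 was low for Cd109 (-0.18, others 0.91 to 1.1). Pre-suppression mouse 3 was low for Gm16433 (0.05, others 0.94 to 1.08), Sqstm1 (8.70, others 8.76 to 8.77), Atf4 (6.41, others 6.61 to 6.64) and Ciart (3.67, others 4.14 to 4.18), and high for Fth1 (10.59, others 10.56). Pre-suppression mouse 4 was high for mt-Nd4 (11.87, others 11.72 to 11.74). Suppressed mouse 4 was high for Bst2, an interferon-induced gene (3.23, others 1.92 to 2.11), and rescued mouse 4 for Mef2c (8.93, others 8.84 to 8.85).

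In list scores, as mean log2 difference from the pre-suppression group, suppressed mouse 4 had an interferon response score of 1.453 against 0.239 to 0.347 in the other 3. Pre-suppression mouse 4 was high for the glucocorticoid response (0.478, others -0.191 to -0.112), heat shock genes (0.354, others -0.143 to -0.074) and mitochondrially encoded genes (0.15, others -0.058 to -0.041), and low for myelin genes (-0.12, others 0.032 to 0.051). Suppressed mouse 3 was low for the glucocorticoid response (0.291, others 0.695 to 0.728), and suppressed mouse 1 high for selective autophagy receptors (0.106, others 0.056 to 0.064). Pre-suppression mouse 3 was high for complement (0.19, others -0.076 to -0.047) and for genes of the olfactory bulb, cerebellum and hindbrain, regions outside the dissected cerebrum (0.78, others -0.354 to -0.168). Rescued mouse 2 was low for immediate early genes (-0.691, others -0.046 to 0.07).

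Ribosomal protein genes were higher in suppressed than in pre-suppression mice, with a median log2 fold change of 0.367. Gene length and GC content as the whole cause were excluded, since the median was still 0.293 (quartiles 0.234 to 0.38) after the trend on both was removed, while 363 genes of like length and GC content had 0.035. A net move of reads from pseudogene copies to the parent genes was excluded as the whole cause, since the 56 pseudogenes tested were themselves higher (median 0.295, quartiles 0.078 to 0.43). Reads shared between copies and parent genes would raise both, so sharing as such is not excluded. Scaling by a few abundant genes was excluded too, since a factor moves all genes of a library alike, while the lower quartile of these genes (0.299) lay above the upper quartile of all other genes (0.126). A steady effect of age was excluded as the whole cause, since the rescued mice, the oldest, had a mean score of 0.036 and at most 0.119 against at least 0.309 in the suppressed mice; a change with Atg101 off stays open as a hypothesis, as does doxycycline, which was not tested apart from it.

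Reactive astrocyte genes set suppressed mouse 3 and rescued mice 2 and 4 apart from the rest of their groups, with scores of 0.112, 0.691 and 0.63. A swap of these libraries between the suppressed group and the others was excluded. The highest Atg101 level of the suppressed libraries was 0.414 CPM and the lowest of all others 6.42 CPM. A swap between rescued and pre-suppression libraries could not be tested this way, since Atg101 was on in both groups. A larger share of astrocytes as the cause of the rise was excluded, since the general astrocyte list had a median log2 fold change of -0.011 (quartiles -0.072 to 0.094) where the reactive list had quartiles of 0.451 to 1.287. What set these mice apart within their groups stays open, and no biological explanation was tested, since the labels give none.

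The homeostatic microglia list was higher in rescued than in pre-suppression mice by camera at the preset correlation (adjusted p = 2.49e-10), but not with an estimated correlation (adjusted p = 0.204), and 0 of its 24 genes passed in edgeR. A larger share of microglia would move all markers of a mouse alike, if no other cells express them. Each mouse's mean over the 24 markers was therefore subtracted. The markers still moved apart more between the groups than in any other of the 35 splits of the 8 mice. The sum over markers of the squared group difference in units of its SE was 65.2 (highest other 52.6, 1 split as large). The SEs came from the fit with the real groups, which favours the real split. This test therefore does not exclude a larger share as the whole cause. A larger share as the whole or part of the cause stays open, and the lists of meninges and fibroblasts (median 0.292) and of perivascular macrophages and leukocytes (0.389) were higher too. Blood left in the tissue was not settled. The haemoglobin share differed by 4.67e-05 percent of counts with an SE of 0.000698. A rise by the median of the list would need 0.000486 if blood supplied all expression of the list, and more if it supplied only a part. That part was not measured, so the comparison decides nothing. Age at sampling cannot be told apart from the history of suppression, because 0 groups were sampled at more than 1 age with the same treatment.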

How the results depend on the processing

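The scaling without mitochondrially encoded and ribosomal protein genes and the fit without suppressed mouse 3 and rescued mice 2 and 4 were chosen after seeing the data, the second on expression, so it is no independent evidence; the counts over other splits of the mice were also chosen after the results were seen. The 3 Atg101 results kept direction and side of the threshold under every alternative run. Between suppressed and pre-suppression mice DESeq2 called 1306 genes, leaving out single libraries gave 290 to 1386, and the fit without the 3 mice 2153, against 714. Counts were 312, 290, 375 and 416 without pre-suppression mouse 1, 2, 3 and 4, and 439, 402, 1386 and 335 without suppressed mouse 1, 2, 3 and 4. The other alternatives gave 677 to 883. Between rescued and suppressed mice the 8 libraries compared gave 86, DESeq2 547, single libraries left out 138 to 385 and the fit without the 3 mice 1229, against 263. Without suppressed mouse 1 or 4 or rescued mouse 1 or 4 there were 175, 163, 138 and 173. Between rescued and pre-suppression mice the same gave 3, 20, 0 to 1 and 0, against 0. Lists called were 0, 1 and 0 with an estimated correlation and 17, 9 and 1 with fry, against 26, 20 and 22, and 23 to 30, 15 to 24 and 20 to 23 with single libraries left out. The median return of 0.70 moved to 0.887 without the 3 mice and lay between 0.625 and 0.789 with single libraries left out. With the suppressed mice split 2 and 2 it averaged 0.517. It was 0.69 to 0.836 or 0.132 to 0.368 there, depending on which side of the split held suppressed mouse 3. Genes still called after rescue were 14 in DESeq2, against 0, and 0 to 1 with single libraries left out (1 without pre-suppression mouse 4 and 1 without suppressed mouse 2). Among results called in either fit, direction reversed only without the 3 mice: for Gm35853 (-1.565 between rescued and suppressed mice, 0.518 with all), the meninges and fibroblast list (-0.006, same comparison), and, between rescued and pre-suppression mice, the nuclear oxidative phosphorylation (-0.008), circadian clock (0.01) and striatum (0.07) lists, while the proteasome list, no longer called, went from a median of 0.064 to -0.001. Values called in neither fit also changed sign, such as Nr4a1 between rescued and suppressed mice (-0.181 with all, 0.395 without suppressed mouse 1). Fewer libraries enter some of these fits; otherwise the cause was not tested. Of the 35 named genes in each comparison fitting the 8 libraries compared ended 1, 14 and 0 calls, limma-voom 6, 4 and 0, and scaling without the 2 gene classes 0; no scaling moved the median of all genes by more than 0.006, so these scalings tested little. In the simulations, run at 1 depth and 4 mice per group, 17.1% of the smallest simulated changes were recovered between suppressed and pre-suppression mice.

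The mouse numbers in the titles did not act as pairs: deviations of same-numbered mice correlated at -0.035 to 0.011, -0.053 to 0.249 and -0.059 to 0.072 in the 3 comparisons, and 0, 1 and 1 of 4 mice correlated best with their own number. With the number as a replicate block 814, 241 and 0 genes were called, and 29, 23 and 23 lists, and 1, 5 and 0 calls of named genes ended.

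Over the 35 splits of the 8 mice, the real split gave 714 genes between suppressed and pre-suppression mice and the highest other 8 (1 split as large). Since the real split counts itself, 1 is the smallest number possible, so chance is made unlikely there but not excluded. For the following counts other splits gave as many, and chance stays open: 263 genes between rescued and suppressed mice (2 splits, highest other 388), and 26, 20 and 22 lists (4, 7 and 2 splits, highest others 30, 26 and 23). For the 0 genes between rescued and pre-suppression mice the splits decide nothing, since all 35 give at least 0 (highest other 2). The split with 388 genes put mice 1 and 3 of both groups against mice 2 and 4, which points to a structure among the samples.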

Other observations

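Of the tests in this part, those of the HIF targets and of the other mRNAs with 3′ iron-responsive elements were fixed before their results were seen; that of the 5′ TOP mRNAs, and the genes named here, were chosen after. The list of HIF targets left out Serpine1, Stc2 and Hmox1, whose values had been seen.

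Besides Tfrc and Fth1, some genes of iron handling moved with Atg101. Slc40a1 (-0.08), Aco2 (0.06) and Alas2 (-0.48), whose mRNAs carry 5′ iron-responsive elements, did not pass with suppression. Nor did Sdhb (-0.01). Control of translation through 5′ elements was not tested by these mRNA levels. Slc11a2, the iron transporter DMT1, went from 41.2 to 60.6 CPM with suppression (log2 fold change 0.56 ± 0.06, edgeR adjusted p = 0.00024) and to 40.1 CPM after rescue (-0.60 ± 0.06, adjusted p = 0.000206). Epas1, which encodes the hypoxia-inducible factor HIF-2α, went from 154 to 241 CPM (0.64 ± 0.06, adjusted p = 8.08e-05) and to 163 CPM (-0.57 ± 0.06, adjusted p = 0.000286). The ferritin light chain Ftl1 rose by 0.29 ± 0.07 with suppression (adjusted p = 0.038) and was at -0.08 ± 0.07 with rescue, which did not pass (adjusted p = 0.691).

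A candidate explanation for the rise of Tfrc and Slc11a2 is a shortage of iron in the cells with activation of HIF targets. It predicted higher HIF targets, and 24 of 32 were positive, with a median log2 fold change of 0.149 (fry p = 0.000542; camera p = 0.00825 with an estimated correlation). Of these 4 passed in edgeR: Vegfa (0.46 ± 0.08), Slc2a1 (0.56 ± 0.10), Pfkfb3 (0.57 ± 0.12) and Mxi1 (0.24 ± 0.06). The quartiles of the list were 0.004 to 0.29. Other targets hardly differed, such as Egln3 (0.03 ± 0.14), Egln1 (-0.05 ± 0.07), Bnip3 (-0.03 ± 0.07) and Ndrg1 (-0.01 ± 0.08). The list cannot tell a shortage of iron from other causes of higher HIF targets. After rescue the 32 targets had a median of -0.044, which neither fry (p = 0.0536) nor camera with an estimated correlation (p = 0.11) called, though camera at the preset correlation gave p = 0.0271. Stabilisation of Tfrc and Slc11a2 through their 3′ iron-responsive elements would also move other mRNAs with such elements, but only Cdc14a (0.292, adjusted p = 0.333) and Cdc42bpa (-0.12, adjusted p = 0.178) could be tested, and neither passed, so this cannot be told apart from other causes with so few genes. Fth1 mRNA rose as well, and protein and iron levels were not analysed here. Fth1, Ftl1 and Sqstm1 are also on the fixed list of targets of the transcription factor NRF2. Of its 30 genes 6 rose and 1 fell with suppression. Camera called this list (adjusted p = 7.1e-05), but not with an estimated correlation (adjusted p = 0.196), and fry called it (adjusted p = 0.00924).

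The rise of ribosomal protein genes may be part of a rise of all mRNAs with a 5′ terminal oligopyrimidine (TOP) sequence, a class of translation genes controlled together. Of 39 TOP mRNAs that encode no ribosomal protein 37 were positive, 13 passed and the median log2 fold change was 0.169 (fry p = 8.52e-07; camera p = 0.000307 with an estimated correlation). Among them were the non-coding host RNAs Gas5 (0.79 ± 0.09, edgeR adjusted p = 0.000206) and Zfas1 (0.89 ± 0.13, adjusted p = 0.00186) and the elongation factor subunit Eef1b2 (0.27 ± 0.05, adjusted p = 0.00521). With rescue 6 fell, with a median of -0.115. Fau and Uba52 were taken off this list after their values were seen, because they encode ribosomal proteins.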
